A study of Mus musculus with 6 samples.

How the data were processed

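RNA of thymocytes from 6 mice, 3 per genotype, was isolated with a column kit (NucleoSpin RNA) and made into libraries with a stranded, poly(A)-selecting messenger RNA kit (TruSeq Stranded mRNA), per the labels' protocols. Reads were handled with STAR 2.5.4b and featureCounts on the mouse genome build GRCm38, per the submitters' processing notes. The version of featureCounts, the annotation release, the strand setting of the counting and the treatment of multi-mapped reads are not given in the sources used here. The deposited table holds raw counts per Ensembl gene identifier, 1 column per library and not normalised, per the file headers and the values, which are whole numbers with a different total in each library. All 55536 identifiers matched the GENCODE M21 annotation of GRCm38, which gave symbols, positions and gene types.

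Identical counts in all 6 libraries were found for 63 of the 18702 genes with at least 60 counts, and 451 genes had a neighbour within 1 Mb whose counts differed by less than 10% in every library. Genes with such a neighbour cannot be told from their copy, and antisense models cannot be told from the overlapping gene while the counting strand is unknown.

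Each library was assigned to its genotype from the labels and to its column by name. Groups, lists of genes, tests and alternatives were fixed before the data were examined, unless stated otherwise. Genes were filtered with edgeR's filterByExpr at its defaults, which left 18690 genes, and library sizes were scaled by TMM. The genotypes were compared with edgeR 4.0.16 (glmQLFit with robust = TRUE and glmQLFTest, R 4.3.3), with no covariate, a Benjamini-Hochberg adjusted p threshold of 0.05 and no fold threshold. Log2 fold changes are labelled knockout over wildtype, and their standard errors were taken from the fold and the F statistic. The common biological coefficient of variation was 18.7%. CPM values are counts scaled by the TMM-adjusted library size.

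Of 36 gene lists written from the series title, the tissue and the cell types a thymus sample can hold, 35 were tested, and the remaining one served as the sex check. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, and again with an estimated correlation and with fry; p-values were Benjamini-Hochberg adjusted over the lists. Members were counted past 0.05 adjusted over all genes and adjusted over the list alone. Some genes stand in more than 1 list, such as Il2ra, Nr4a1, Cd5 and Gzma. A library's list score is the mean log2 CPM of the members minus the mean over the libraries.

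Il3ra, Csf2rb, Csf2rb2 and Il3 were named in any case. Each way, the 10 genes of largest absolute log2 fold change were named among those with an adjusted p under 0.05, a mean of at least 1 CPM, a symbol that is no clone name and no overlap between genotypes; where fewer passed, genes of smallest unadjusted p under the same conditions filled the 10 and are described as not past the threshold. Up to 4 members of smallest unadjusted p were eligible in each list described. Nbea, 5830416I19Rik and the 7 Gm models fall outside this rule and were named after their values were seen, to complete the 17 genes, and so were the extra named members of lists and single-library values.

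The precision is set by the totals of 55747682 to 82684219 counts. A count of 0 in a library allows up to 3 counts, which is 0.0357 to 0.0519 CPM. Such floors and the counting intervals cover counting error only, since the reads carry no molecular identifiers. Counts were simulated with the means and the trended dispersions of the real libraries, each gene independently. Changed genes were drawn from those with an average log2 CPM above 0. The genotype test over 18690 genes recovered 46.8% of genes changed 1.5-fold, 84.6% of those changed 2-fold and 99.0% of those changed 4-fold. Of its 539 calls in these simulations, 3.15% were of unchanged genes. Variation that genes share within a library was not simulated, so these percentages can differ in the real libraries.

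Shares of counts were compared with exact permutation tests and called genes near Il3ra with Fisher's exact test. Libraries of 1 genotype differed by far more than sampling noise (chi-square per degree of freedom of 41.8 to 98.6 between replicates), so none was taken as a duplicate. The alternatives set beforehand were DESeq2 1.42.0, limma-voom, 2 other scalings, 2 other filters, a replicate block, the omission of each library, and other windows around Il3ra. A covariate for the Xist-high library of each genotype, a fit without these 2 libraries and a fit without genes that have a near-equal neighbour were added after the data were seen.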

Results

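Messenger RNA of mouse thymocytes, the developing T cells of the thymus, was counted per gene in 6 libraries. Per the labels, 3 came from wildtype mice (Il3ra+/+) and 3 from mice lacking the alpha chain of the receptor for interleukin-3 (Il3ra-/-), 1 library per mouse, with no treatment. Total counts were 60601819, 55747682 and 66534218 in wildtype replicates 1 to 3. They were 59135254, 82684219 and 72538282 in the replicates labelled knockout. Of the 55536 genes in the table, 18690 had enough counts to be tested. The comparison asks how thymocytes of the 2 genotypes differ in steady state, and the series title names regulatory T cells, mechanobiology and tissue egress as its themes. All coordinates are on GRCm38. Values are TMM-normalised CPM (counts scaled by library size), as mean ± SD.

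Il3ra, the targeted gene, was not lower in the libraries labelled knockout. Il3ra (ENSMUSG00000068758, chromosome 14, 14346275 to 14356011, plus strand) had 465, 376 and 399 counts in the wildtype libraries and 481, 673 and 514 in those labelled knockout. These gave 6.81 ± 0.88 CPM in wildtype and 7.78 ± 0.35 CPM in the labelled knockout (SD, n = 3 each), a fold of 1.14 with a 95% interval of 0.932 to 1.40 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.585). The counts are summed over the whole gene and the deleted part of the allele is not given in the sources used here, so a transcript that lacks an exon would still be counted. The genotype labels are therefore not checked by this gene, and every direction below is that of the libraries labelled knockout.

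The partner chains of the receptor varied mainly among the libraries labelled knockout. Csf2rb, the common beta chain, had 142, 516 and 747 counts in labelled knockout replicates 1 to 3 and 262, 277 and 330 in wildtype. Csf2rb2, the mouse beta chain specific to interleukin-3, had 129, 352 and 604 counts against 164, 174 and 173. Their folds of 1.35 and 1.79 did not pass edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.726 and 0.421), and without labelled knockout replicate 3 the log2 fold of Csf2rb turned to -0.15. The scores of the macrophage list (-0.67, 0.29 and 0.80) and dendritic cell list (-0.71, 0.37 and 0.53) rose in the same order over labelled knockout replicates 1 to 3. Whether the cell content of the libraries set the counts of these chains was not tested. Il3, the ligand, had 0 counts in all 6 libraries, where the limit that a count of 0 allows was 0.0357 to 0.0519 CPM per library. Of the 8 tested members of the interleukin-3 receptor list, 0 passed over all genes and 0 when adjusted over the list alone, with 0 at an unadjusted p under 0.05 by edgeR and 0 by DESeq2. Without the low-count filter 1 of 10 members rose over all genes. The list's median log2 fold was 0.08 (camera adjusted p = 0.749), and Csf2ra and Stat5b had folds of 1.15 and 0.893. The 16 STAT5 target genes, transcripts known to respond to cytokine receptors, had a median log2 fold of -0.08 (camera adjusted p = 0.528). Within that list Bcl6, a transcriptional repressor, fell from 171 ± 18.2 to 123 ± 2.87 CPM and Myc, a growth regulator, rose from 61.6 ± 5.59 to 85.4 ± 6.83 CPM when adjusted over the list alone (edgeR, Benjamini-Hochberg adjusted p = 0.00616 for each, against 0.138 and 0.139 over all genes). Without replicate 1 of each genotype their adjusted p-values over all genes were 0.0333 and 0.0508 by edgeR. Over all genes 1 member rose and 1 fell by DESeq2, and 2 rose and 1 fell by edgeR without the low-count filter.

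Transcripts of 17 genes differed between the genotypes, 3 higher and 14 lower in the libraries labelled knockout (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Slc15a2, a peptide transporter (chromosome 16, 36750177 to 36784962), fell from 164 ± 25.4 to 72.9 ± 6.99 CPM, 2.25-fold lower. Gramd3, a GRAM domain gene (chromosome 18, 56400337 to 56503792), fell 1.86-fold from 40.7 ± 6.10 to 21.9 ± 0.335 CPM, and Smoc1, a secreted calcium-binding protein (chromosome 12, 81026808 to 81186414), fell 1.94-fold from 29.5 ± 3.47 to 15.2 ± 2.19 CPM. The transmembrane protein genes Tmem254a, Tmem254b and Tmem254c (chromosome 14, 25923300 to 26207041) fell 2.44-fold, 2.44-fold and 2.45-fold, with Tmem254a at 29.6 ± 2.70 CPM in wildtype and 12.1 ± 0.648 CPM in the labelled knockout. The long noncoding RNA 5830416I19Rik (chromosome 5, 64044978 to 64050228) fell 5.23-fold, from 4.32 ± 0.476 to 0.826 ± 0.0792 CPM. Ide, the insulin-degrading protease (chromosome 19, 37268743 to 37337852), rose 1.72-fold from 47.5 ± 3.45 to 81.6 ± 7.04 CPM. Fgfbp3, a binding protein of fibroblast growth factors on the same chromosome (36917550 to 36919615), rose 3.43-fold from 0.913 ± 0.271 to 3.13 ± 0.181 CPM. Nbea, a membrane traffic protein (chromosome 3, 55625195 to 56183701), rose 5.63-fold from 0.296 ± 0.0212 to 1.67 ± 0.241 CPM. In each of these 10 genes all 3 libraries of one genotype lay on one side of the other 3.

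**Figure D1:**
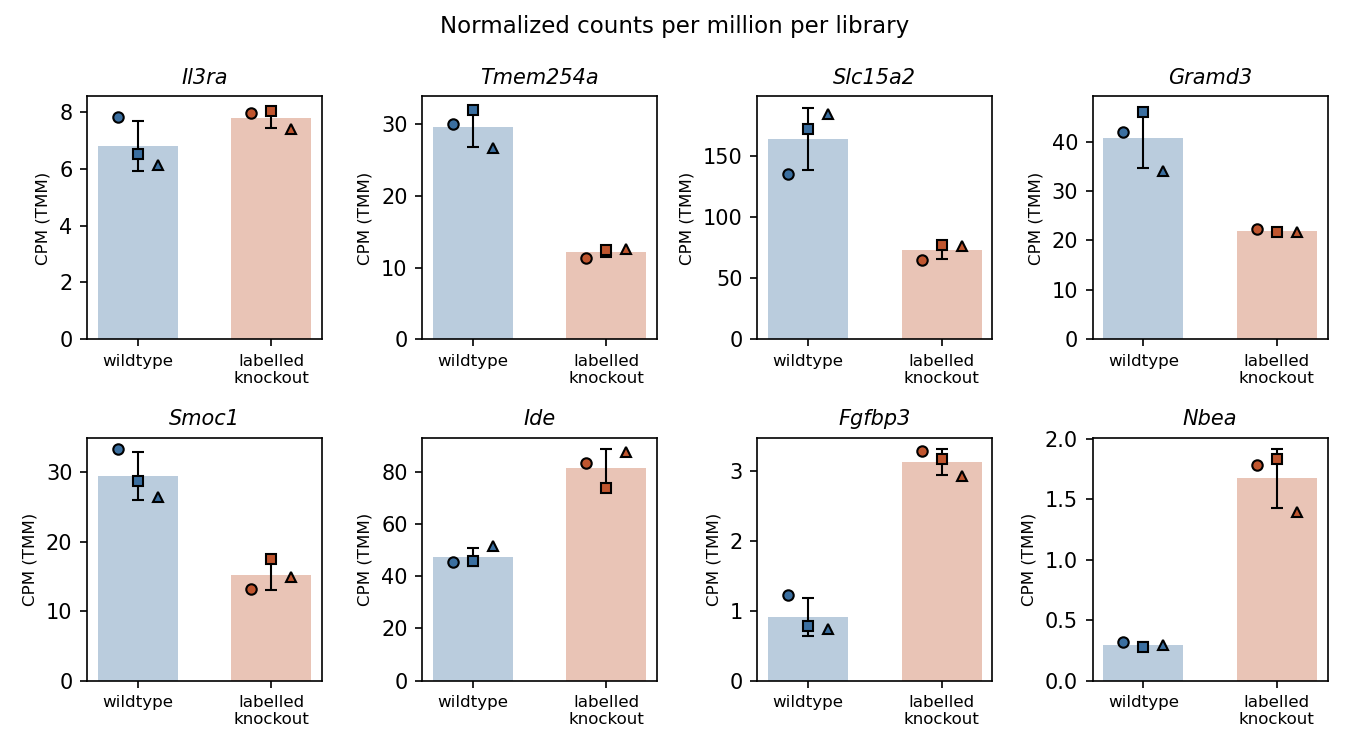
TMM-normalised CPM of 8 genes in each library, with the gene named over each panel. Bars show the mean of 3 libraries and error bars the SD; circles, squares and triangles are replicates 1, 2 and 3, in blue for wildtype and orange for the labelled knockout. Il3ra overlaps between the genotypes, whereas Tmem254a, Slc15a2, Gramd3 and Smoc1 are lower and Ide, Fgfbp3 and Nbea higher in all 3 libraries labelled knockout.

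The other 7 genes that fell lie between 69348897 and 69683286 on chromosome 14, a stretch that the annotation shows as repeated gene copies. Gm16867 (69363504 to 69503362), a protein-coding model, fell 17.6-fold from 15.6 ± 5.73 to 0.877 ± 0.323 CPM, and its near-equal copy Gm27177 fell 17.4-fold. In wildtype replicates 1 to 3 Gm16867 had 16.3, 20.9 and 9.48 CPM and Gm38378 had 0.855, 0.934 and 0.460 CPM. Among the wildtype libraries all 7 models were lowest in replicate 3. The cause of this spread within wildtype was not tested. The antisense models Gm27176 and Gm27221 fell 18.0-fold and 17.9-fold from 0.905 ± 0.306 and 0.899 ± 0.301 CPM. Gm38378 and Gm37513, with identical counts in every library, had 135 counts over the wildtype libraries and 0 in the labelled knockout, at least 52.7-fold lower against a floor of 3 counts over the group. The pseudogene Gm21451 had 159 and 3 counts. This is a ratio of 0.0161 with a 95% Clopper-Pearson counting interval of 0.00329 to 0.0479. Adjusted p-values of the 7 were 0.00333 to 0.0338 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Gm21451 and Gm38378 overlap Gm16867 and Gm37513 overlaps Gm27177, and the counting strand is not given, so these models are not independent. Of the 17 genes, 9 (Tmem254a, Tmem254b, Tmem254c, Gm16867, Gm27177, Gm27176, Gm27221, Gm38378 and Gm37513) have a neighbour within 1 Mb whose counts differ by less than 10% in all 6 libraries, and their reads cannot be assigned to 1 copy.

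At the unadjusted level 2730 genes had p under 0.05, 1497 higher and 1233 lower, against 934.5 by chance. In 3787 tested genes (20.3%) the genotypes did not overlap, against 10% by chance with 3 libraries a side. DESeq2's Wald test called 594 genes (392 higher, 202 lower), with 11 of the 17 among them. Without the low-count filter edgeR called 840 (531 higher, 309 lower). Without replicate 1 of each genotype edgeR called 762 (394 higher, 368 lower), and without genes that have a near-equal neighbour called 7 (2 higher, 5 lower). Leaving out 1 library at a time gave 8 calls without wildtype replicate 2 and 29 without labelled knockout replicate 1, and 5 genes (5830416I19Rik, Slc15a2, Tmem254a, Tmem254b and Tmem254c) passed in all 6 such fits.

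Replicate 1 of each genotype stood apart by sex-linked transcripts, which the labels do not mention. Xist, the noncoding RNA of the inactive X chromosome, had 88078 counts in wildtype replicate 1 and 128236 in labelled knockout replicate 1, and 8 to 57 in the other 4 libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 to 5 counts in these 2 libraries and 1724 to 11226 in the others. Each genotype therefore held 1 Xist-high and 2 Xist-low libraries.

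Chromosome 14, which carries Il3ra, held 10 of the 17 genes among its 836 tested genes, against 7 of 17854 elsewhere. These 10 lie at 2 of 8 places and include near-equal copies and overlapping models, so a test that takes them as independent genes does not hold. With each set of near-equal copies counted once, 12 sets were called, 5 of them on chromosome 14. None of the 113 tested genes within 10 Mb of Il3ra passed edgeR's adjusted threshold; 16 of them had an unadjusted p under 0.05, an odds ratio of 0.964 (Fisher's exact p = 1). Tmem254a was the nearest, 11.6 Mb from Il3ra, so a window of 20 Mb held the 3 Tmem254 genes among its 216 tested genes. As near-equal copies these 3 are not independent calls.

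**Figure D2:**
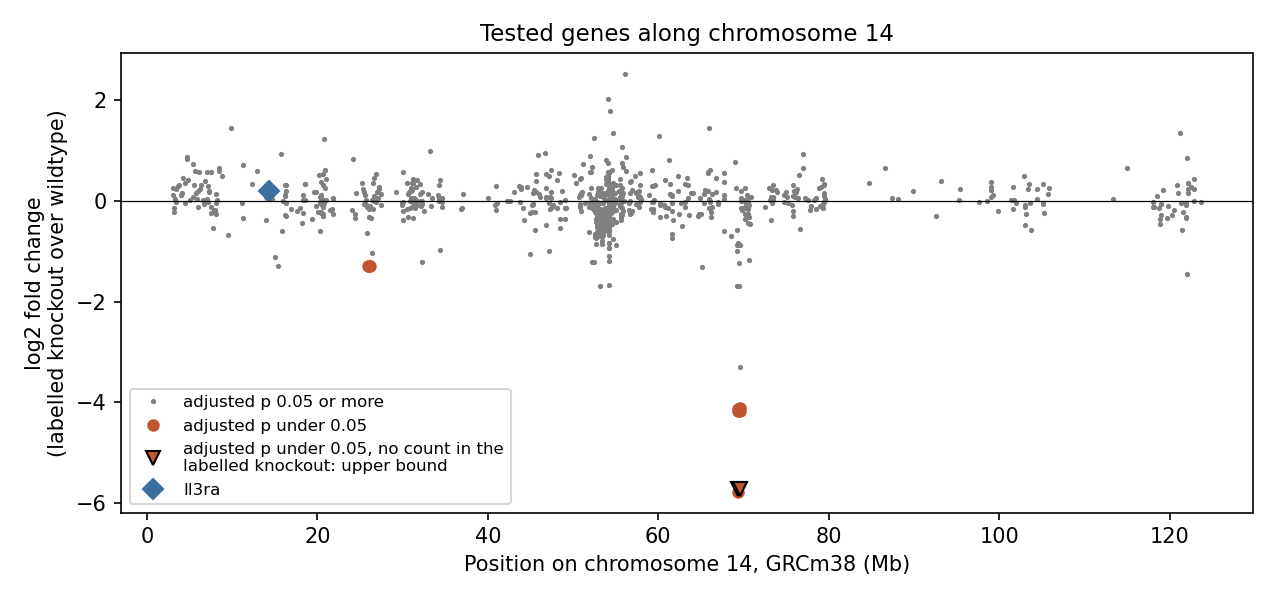
Log2 fold change of each tested gene on chromosome 14 against its start (Mb, GRCm38), labelled knockout over wildtype. Grey points are genes at an adjusted p of 0.05 or more, orange points genes below it, orange triangles the upper bound of Gm38378 and Gm37513, which had no count in the labelled knockout, and the blue diamond Il3ra. The orange points form 1 group of Tmem254 genes and another between 69348897 and 69683286, and none lies within 10 Mb of Il3ra.

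Genes that did not overlap between genotypes were next taken by smallest unadjusted p above the adjusted threshold. Fancd2, a DNA crosslink repair gene, had 18.7 ± 3.30 CPM in wildtype and 32.2 ± 3.86 in the labelled knockout, and Tipin, which protects replication forks, had 40.5 ± 6.26 and 65.7 ± 7.60 CPM. Cnbd2 (fold 1.99), Camk2b (2.90), Uaca (2.0), Rab44 (1.61), Ccdc18 (1.71) and the arginine deiminase gene Padi4 (1.64) had higher means in the labelled knockout. On the lower side stood Rab6b, a Golgi traffic GTPase (fold 0.650), Spsb1 (0.606), the G protein regulator Rgs14 (0.695) and Nckap5l (0.666). None of these 12 passed edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p = 0.0878 to 0.132). Without replicate 1 of each genotype some of them passed that test, among them Cnbd2, Fancd2, Rab6b and Spsb1 (adjusted p = 0.0145, 0.0196, 0.0330 and 0.0354).

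Gene lists fixed beforehand described the rest. No member of the 35 tested lists passed edgeR's test over all genes, so counts of members below are adjusted over the list alone beside 0 over all genes. By camera with a preset correlation of 0.01, 17 of the 35 lists passed a Benjamini-Hochberg adjusted p of 0.05. With an estimated correlation 0 did (smallest adjusted p = 0.609), and 0 did by fry (smallest adjusted p = 0.368). Splits of the 6 libraries that mix the genotypes gave 9 to 20 lists by camera at the preset correlation. A list called higher or lower below is therefore described in these libraries, and a genotype difference is not established by that test.

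Genes of cell division had higher transcript levels in the libraries labelled knockout. In the cell cycle list all 37 members were fitted higher and 37 rose when adjusted over the list alone, with a median fold of 1.43 (camera adjusted p = 1.02e-32; adjusted p = 0.609 with an estimated correlation). Cdc6, a licensing factor of replication origins, went from 37.9 ± 5.56 to 59.2 ± 8.88 CPM, Ccnb1, the mitotic cyclin B1, from 67.6 ± 10.6 to 105 ± 15.1 CPM, and Mcm6, a subunit of the replicative helicase, from 206 ± 14.8 to 286 ± 28.6 CPM. Of the 37 members, DESeq2 called 30 and edgeR without replicate 1 of each genotype called 8, all higher. In the tubulin and kinesin list 10 of 28 members rose when adjusted over the list alone (median log2 fold 0.40; camera adjusted p = 1.34e-07; adjusted p = 0.664 with an estimated correlation), led by the mitotic motor Kif15 at 73.9 ± 11.6 and 123 ± 24.4 CPM. Its leading members Kif15, Kif20a, Kif2c and Kif18a are motors of the mitotic spindle. Histone genes had a median log2 fold of 0.30, with 57 of 62 fitted higher and 0 passing when adjusted over the list alone. Their camera adjusted p was 1.22e-06, and 0.664 with an estimated correlation. Unlike the cell cycle scores, the histone scores overlapped between genotypes, at -0.11 in labelled knockout replicate 1 and 0.04 in wildtype replicate 1. The p53 and apoptosis list was lower by camera (median log2 fold -0.17; adjusted p = 0.0294; adjusted p = 0.664 with an estimated correlation), with 2 members that rose and 4 members that fell when adjusted over the list alone. Zmat3 had 20.1 ± 4.06 and 12.4 ± 0.800 CPM and the death inducer Bbc3 22.4 ± 3.34 and 15.3 ± 1.44 CPM, whereas the cell cycle inhibitor Cdkn1a had 3.80 ± 0.226 and 5.98 ± 0.802 CPM. The p53 call ended without wildtype replicate 2 or labelled knockout replicate 1 (camera adjusted p = 0.0912 and 0.0893).

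The lists of thymocyte stages were each compared between the genotypes. The double-negative list, genes of the earliest thymocytes, was higher (13 of 14 fitted higher, median log2 fold 0.38; camera adjusted p = 0.0107; adjusted p = 0.664 with an estimated correlation), with Kit at 6.92 ± 0.615 and 10.5 ± 2.91 CPM, and 0 members passed when adjusted over the list alone. Kit overlapped between the genotypes, and the member fitted lower, Dtx1, had a fold of 0.821. The list's mean score was lowest of all libraries in labelled knockout replicate 1 (-0.28) and highest in replicate 3 (0.50), with 0.25 in replicate 2. Macrophage scores (-0.67, 0.29 and 0.80) and B cell scores (-0.70, 0.16 and 0.51) rose in the same order over labelled knockout replicates 1 to 3. The list is therefore not shown to measure early thymocytes alone. The double-positive list was lower (11 of 13 fitted lower, median log2 fold -0.19; camera adjusted p = 0.00805; adjusted p = 0.664 with an estimated correlation), again with 0 members past the test on the list alone. Within it Cd8b1 had 1296 ± 72.0 and 1051 ± 40.3 CPM, and Cd4 1284 ± 30.2 and 1044 ± 89.3 CPM. The single-positive list was lower (median log2 fold -0.13; camera adjusted p = 0.0180; adjusted p = 0.664 with an estimated correlation), and 3 of 18 members fell when adjusted over the list alone. These were Zbtb7b, the regulator of the CD4 lineage (39.7 ± 4.83 and 28.1 ± 3.26 CPM), the diacylglycerol kinase Dgka (557 ± 26.4 and 400.0 ± 61.1 CPM) and Cd5, a dampener of antigen receptor signals (282 ± 24.4 and 224 ± 9.09 CPM). Genes induced by antigen receptor signals in selection were lower (18 of 21 fitted lower, median log2 fold -0.16; camera adjusted p = 0.00244; adjusted p = 0.664 with an estimated correlation), and Nr4a1 alone fell when adjusted over the list alone (111 ± 11.9 and 77.4 ± 13.2 CPM). The double-negative call ended without wildtype replicate 1, labelled knockout replicate 2 or labelled knockout replicate 3 (camera adjusted p = 0.0599, 0.0608 and 0.158). Its median log2 fold was 0.44, 0.36 and 0.11 in these fits, and 0.60 without labelled knockout replicate 1. The single-positive call ended without wildtype replicate 1, wildtype replicate 3 or labelled knockout replicate 1 (camera adjusted p = 0.197, 0.102 and 0.213), at medians of -0.05, -0.08 and -0.11. The selection call ended without labelled knockout replicate 1 (camera adjusted p = 0.0608). Without replicate 1 of each genotype both calls ended, with medians of -0.01 and -0.13 (camera adjusted p = 0.697 and 0.103). Markers of gamma delta T cells were fitted higher in all 9 members, and 8 rose when adjusted over the list alone. Their median fold was 1.40 (camera adjusted p = 1.34e-07, and 0.609 with an estimated correlation). Trdc, the constant gene of the delta chain, had 93.4 ± 17.9 and 130 ± 19.6 CPM, and Sox13 11.3 ± 1.67 and 16.9 ± 2.85 CPM.

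Regulatory T cell genes did not pass as a group, which does not show that they were unchanged. The 21 tested members had a median log2 fold of 0.05 (camera adjusted p = 0.425), and Nrp1, a surface receptor of thymus-derived regulatory T cells, rose when adjusted over the list alone, from 26.2 ± 3.53 to 37.5 ± 3.85 CPM (edgeR, Benjamini-Hochberg adjusted p = 0.0297, and 0.151 over all genes). Il2ra and Ctla4 had folds of 1.29 and 1.34 and did not pass. Il2ra is also a member of the double-negative and STAT5 lists, and counts of thymocyte libraries do not measure regulatory T cells alone. The egress and chemokine receptor list had a median log2 fold of -0.07 and a mean of 0.02, opposite in sign, and did not pass (camera adjusted p = 0.227). Its members Plxnd1, a semaphorin receptor (666 ± 53.2 and 482 ± 36.1 CPM), and Ccr9, a homing receptor for the thymus and gut (814 ± 53.2 and 617 ± 65.7 CPM), fell when adjusted over the list alone (edgeR, Benjamini-Hochberg adjusted p = 0.0224 and 0.0430, and 0.151 and 0.176 over all genes). Without wildtype replicate 2 or without labelled knockout replicate 3 this list passed camera as lower (adjusted p = 0.00698 and 0.0421). Without replicate 1 of each genotype 4 of its 18 members rose and 1 fell over all genes, with a median log2 fold of 0.04 (camera adjusted p = 0.222).

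Adhesion genes were lower by a small amount. The integrin and adhesion list had a median log2 fold of -0.15 (camera adjusted p = 0.0486; adjusted p = 0.664 with an estimated correlation), with 1 member that rose and 3 members that fell when adjusted over the list alone. The beta 2 integrin chain Itgb2 had 330 ± 12.0 and 256 ± 10.2 CPM, its alpha partner Itgal 758 ± 55.1 and 598 ± 24.7 CPM, and the Rap1 inactivator Sipa1 200 ± 12.5 and 159 ± 11.9 CPM, whereas the adhesion linker Vcl had 3.19 ± 0.400 and 4.91 ± 0.459 CPM. The call ended without wildtype replicate 1, without wildtype replicate 3 and without labelled knockout replicate 1 (camera adjusted p = 0.103, 0.242 and 0.213). It also ended without replicate 1 of each genotype (median log2 fold -0.09, camera adjusted p = 0.267) and with library size as the only scaling (0.0501). The actin and mechanics list had 35 of 49 members fitted lower (median log2 fold -0.08) and did not pass camera (adjusted p = 0.102; without wildtype replicate 2 it passed as lower, adjusted p = 0.00748), with 0 members past the test on the list alone. Its nuclear lamina gene Lmnb1 had 268 ± 20.1 and 348 ± 33.8 CPM and the actin nucleator Diaph1 317 ± 3.01 and 268 ± 9.98 CPM. By fry's mixed test, which asks whether members change in either direction, the adhesion, actin and STAT5 lists passed (Benjamini-Hochberg adjusted p = 0.00506, 0.0287 and 0.0287).

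Cholesterol synthesis genes were higher, with 15 of 17 fitted higher and 7 that rose when adjusted over the list alone (median fold 1.26; camera adjusted p = 1.78e-08; adjusted p = 0.664 with an estimated correlation). Idi1 had 24.9 ± 4.56 and 39.8 ± 4.08 CPM, and the squalene epoxidase Sqle 15.9 ± 2.74 and 25.5 ± 3.07 CPM. Genes of oxidative phosphorylation (71 of 81 fitted higher, median log2 fold 0.12; camera adjusted p = 0.000109; adjusted p = 0.744 with an estimated correlation) and ribosomal protein genes (79 of 88, 0.12; 0.000588; adjusted p = 0.757 with an estimated correlation) were higher as sets, with 0 members past the test on the list alone. With 1 library left out, the oxidative phosphorylation median ranged from 0.071 (without labelled knockout replicate 3) to 0.20 (without wildtype replicate 1). Glycolysis genes (median log2 fold 0.11, camera adjusted p = 0.336) and genes of the mitochondrial genome (0.13, adjusted p = 0.0892) did not pass. The ribosomal call ended without wildtype replicate 2 or labelled knockout replicate 3 (camera adjusted p = 0.0626 and 0.102), and mitochondrial genes passed as higher without wildtype replicate 1, wildtype replicate 3 or labelled knockout replicate 1 (0.0344, 0.0264 and 0.00865). Immediate early and heat shock genes were lower (15 of 20 fitted lower, median log2 fold -0.19; camera adjusted p = 0.000666; adjusted p = 0.609 with an estimated correlation), and Nr4a1 fell when adjusted over the list alone. The heat shock gene Hspa1a had 49.0 CPM in wildtype replicate 2, 5.57 and 11.4 in the other wildtype libraries and 1.31 to 3.24 in the labelled knockout. The list's score was -0.07, 0.49 and 0.23 in wildtype replicates 1 to 3 and -0.33, -0.06 and -0.27 in the labelled knockout. Glucocorticoid response genes were lower (median log2 fold -0.04; camera adjusted p = 0.0294; adjusted p = 0.664 with an estimated correlation), with Ddit4, Sgk1 and Per1 lower when adjusted over the list alone. Ddit4 had 88.3 ± 18.1 and 57.7 ± 6.50 CPM, and the glucocorticoid call ended without labelled knockout replicate 1 or wildtype replicate 3 (camera adjusted p = 0.338 and 0.0882). Interferon response genes and effector cytokine genes did not pass (camera adjusted p = 0.528 and 0.636), and their median, mean and test differed in sign. Without labelled knockout replicate 2 the interferon list passed as lower (median log2 fold -0.19, adjusted p = 0.0180). In the effector cytokine list Gzma, a granule protease, rose from 30.3 ± 4.90 to 49.1 ± 8.84 CPM when adjusted over the list alone (edgeR, Benjamini-Hochberg adjusted p = 0.00639).

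**Figure D3:**
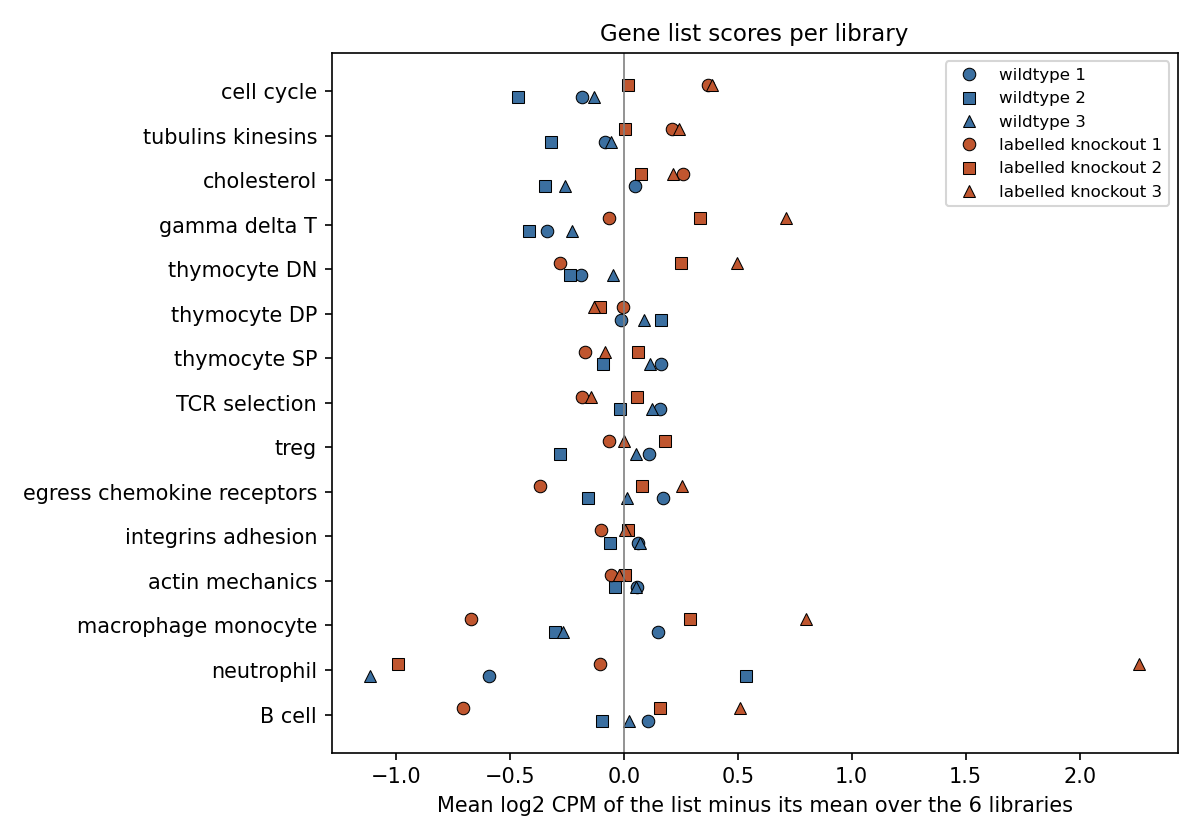
Score of 15 gene lists in each library, the mean log2 CPM of the list's members minus its mean over the 6 libraries. Blue symbols are wildtype and orange symbols labelled knockout, and circles, squares and triangles are replicates 1, 2 and 3. The cell cycle scores of the 3 libraries labelled knockout (0.02 to 0.39) lie above those of wildtype (-0.46 to -0.13). Labelled knockout replicates 1 and 3 lie at opposite ends of the macrophage and B cell scores.

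Markers of other cells varied between single libraries. The neutrophil list was higher by camera (median log2 fold 1.24; adjusted p = 0.0136; adjusted p = 0.744 with an estimated correlation), and without labelled knockout replicate 3 its median was -0.31. The call also ended without wildtype replicate 1 or 3 (camera adjusted p = 0.103 and 0.214). S100a8, an abundant granulocyte protein, had 79.1 CPM in that library and 6.27 to 19.8 in the other 5. The myeloid progenitor genes Elane and Mpo had 4.86 and 11.7 CPM there and at most 0.793 and 1.47 elsewhere. The macrophage list (median log2 fold 0.39, camera adjusted p = 0.0847), the dendritic cell list (0.15, 0.639) and the list of basophils, mast cells and eosinophils (0.49, 0.129) did not pass. Their scores were lowest of all libraries in labelled knockout replicate 1 and highest in replicate 3, for macrophages -0.67 and 0.80. B cell genes (-0.03, camera adjusted p = 0.887) followed the same order among those libraries (-0.70 and 0.51), and plasma cell genes (0.08, 0.721) did not pass. In both lists the median and the mean or test differed in sign. Natural killer (0.17, camera adjusted p = 0.293), innate-like T cell (0.13, 0.749), thymic epithelium (0.27, 0.0893) and stroma lists (0.28, 0.196) did not pass. Cpa3, a mast cell protease, and Pdgfrb and Cdh5, genes of pericytes and endothelium, rose when adjusted over their lists alone, Cpa3 from 4.30 ± 1.39 to 8.22 ± 2.27 CPM. Pdgfrb had 5.71 ± 0.615 and 8.72 ± 1.35 CPM. Cdh5 had 0.369 to 0.450 CPM in wildtype and 0.677, 0.810 and 2.96 in labelled knockout replicates 1 to 3, and its log2 fold of 1.81 was 0.82 without replicate 3. Red cell genes were fitted lower in all 8 tested members, with 0 past the test on the list alone. Their median log2 fold was -0.66 (camera adjusted p = 0.0209, and 0.664 with an estimated correlation). Car2 had 6.45 ± 2.22 and 4.58 ± 1.12 CPM, but Alas2 had 0.330 ± 0.106 and 0.211 ± 0.0494 CPM and Klf1 0.197 ± 0.0727 and 0.143 ± 0.0348 CPM. The call ended without wildtype replicate 2, wildtype replicate 3 or labelled knockout replicate 1 (camera adjusted p = 0.0561, 0.0781 and 0.204). Without labelled knockout replicate 1, the macrophage, dendritic cell, basophil, B cell, natural killer, innate-like T cell and thymic epithelium lists passed as higher (camera adjusted p = 4.81e-08 to 0.0326). The macrophage and thymic epithelium lists also did without wildtype replicate 1 (camera adjusted p = 0.0151 and 0.0128), and without labelled knockout replicate 3 B cell genes passed as lower (0.0101).

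Shares of each library's counts were compared by exact permutation tests, which with 3 against 3 libraries cannot go below p = 0.1 (two-sided) and so cannot call a difference at 0.05. Ribosomal protein genes took 3.71 ± 0.302% in wildtype and 4.02 ± 0.286% in the labelled knockout (SD, n = 3 each; exact p = 0.2), mitochondrial genes 11.3 ± 1.56% and 12.3 ± 1.65% (exact p = 0.6), haemoglobin genes 0.00359 ± 0.00255% and 0.00196 ± 0.00150% (exact p = 0.4) and the 20 most abundant genes 18.6 ± 2.31% and 19.7 ± 2.48% (exact p = 0.6).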

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

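The test in this part was chosen only after the sex-linked transcripts had been seen. In 128 of 18690 genes the genotype difference itself differed between the Xist-high libraries (replicate 1 of each genotype) and the Xist-low libraries (replicates 2 and 3), by the interaction term of edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The fold of labelled knockout over wildtype was larger among the Xist-low libraries in 95 of these genes and smaller in 33. The genes named here were chosen after their values were seen. Igha, an antibody heavy chain gene, had 63.3 CPM in wildtype replicate 1 and 15.8 in labelled knockout replicate 1, against 34.8 and 37.0 in the other wildtype libraries and 55.0 and 59.8 in the other labelled knockout libraries. H2-Aa, a class II antigen presentation gene, had 80.3 and 31.8 CPM in the Xist-high pair, against 72.8 and 72.9 in wildtype and 86.0 and 103 in the labelled knockout. Lpin1, a lipid metabolism gene, went the other way, with 27.4 and 98.8 CPM in the Xist-high pair, 32.8 and 26.4 in wildtype and 23.2 and 19.1 in the labelled knockout. The heat shock genes Hsph1, Dnaja1 and Hsp90aa1 were also among the 33. Hsph1 had 65.6 and 109 CPM in the Xist-high pair, 228 and 160 in wildtype and 69.4 and 77.1 in the labelled knockout. The Xist-high side holds 1 library per genotype, so its difference has no replicate, and the test takes its spread from the Xist-low libraries alone. It does not separate sex from any other property of these libraries. Labelled knockout replicate 1 also had the lowest B cell, macrophage and dendritic cell scores of all 6 libraries (-0.70, -0.67 and -0.71).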

How the results depend on the processing

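The covariate for the Xist-high library, the fit without the Xist-high pair and the fit without near-equal neighbours were chosen only after the data had been seen. The counts of 3 genes higher and 14 lower stayed within 1.5 times under limma-voom (3 and 11), DESeq2 size factors (3 and 14), library size alone (4 and 14) and the Xist-high covariate (2 and 10). They became 392 and 202 with DESeq2, 531 and 309 without a low-count filter, 394 and 368 without the Xist-high pair, 3 and 9 with a minimum of 1 CPM in 3 libraries, and 2 and 5 without near-equal neighbours. When 1 library was left out they ranged from 1 to 15 and from 7 to 18. There was 1 higher without wildtype replicate 2 or 3, there were 15 and 12 higher without labelled knockout replicate 1 or 2, and there were 9 and 7 lower without wildtype replicate 1 or 2. Of the 840 genes called without the filter 814 were also tested with it, and 513 were shared with the DESeq2 calls; DESeq2 and the fit without the Xist-high pair shared 219. The CPM minimum and the removal of near-equal neighbours took called lower genes out of the test by construction, and otherwise the cause was not tested. Only 5830416I19Rik and Slc15a2 passed in all of these fits. With the replicate block the counts were 1 and 8, and 15 lists passed, without the adhesion list (median -0.15) and the neutrophil list (median 0.52; camera adjusted p = 0.0593 each). Deviations of same-numbered libraries correlated at -0.107, 0.0293 and -0.115, and wildtype replicate 1 correlated best with labelled knockout replicate 3 (0.163), so the numbers were not taken as pairs.

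The 17 lists called by camera became 0 with an estimated correlation and 0 by fry; the other alternatives gave 13 to 22. Within 20 Mb of Il3ra 3 genes were called, against 0 within 10 Mb, since the wider window takes in the Tmem254 genes.

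Of 162 named genes, 155 kept their direction under all alternatives. The log2 fold turned negative without labelled knockout replicate 3 for the other 7. Ranges over the omitted libraries were -0.15 to 0.83 for Csf2rb, -0.36 to 1.04 for Prg2, -0.30 to 0.73 for Hdc, -0.18 to 1.87 for S100a8, -0.082 to 0.26 for Derl3, -0.26 to 0.89 for Sdc1 and -0.32 to 0.39 for Mzb1. Sdc1 did so also without wildtype replicate 2 or 3, and Mzb1 without wildtype replicate 3. Median log2 folds of lists changed sign with an omitted library for the interleukin-3 receptor (-0.029 to 0.18), regulatory T cells (-0.043 to 0.19), egress (-0.16 to 0.035), interferon response (-0.19 to 0.27), effector cytokines (-0.034 to 0.37), glucocorticoid response (-0.23 to 0.025) and glycolysis (-0.0086 to 0.21). Among markers of other cells they did so for B cells (-0.23 to 0.26), plasma cells (-0.26 to 0.26), macrophages (-0.031 to 0.70), neutrophils (-0.31 to 1.74), dendritic cells (-0.069 to 0.46), basophils (-0.30 to 0.93), stroma (-0.070 to 0.22), natural killer cells (-0.021 to 0.50) and innate-like T cells (-0.087 to 0.56). Without the Xist-high pair the medians of STAT5 targets (0.037), egress (0.044), actin (0.013), effector cytokines (0.15) and B cells (0.38) changed sign, and the interferon median did with the replicate block (-0.015) and with the Xist-high covariate (-0.014). The difference in the share of the 20 most abundant genes ranged from -0.199 to 2.23 percentage points with an omitted library. The cause of these changes of sign was not tested. In the simulated genotype comparison over 18690 genes, 46.8% of 1.5-fold changes were recovered. The genes simulated as changed left out the least abundant ones, and genes varied independently. At this depth and number of libraries many changes of that size would therefore not be detected.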

Other observations

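Except for the removal of trends in GC content and length, the splits of the 6 libraries and the windows around Il3ra (for the splits and windows the reading was set after the results), the tests in this part were chosen only after the results were seen.

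Among the 4 Xist-low libraries alone, 2 per genotype, several lists passed that had not passed over all 6. Macrophage genes had a median fold of 1.76, and 4 of 14 members rose over all genes (edgeR's quasi-likelihood test; camera adjusted p = 7.05e-09). Natural killer genes had a median fold of 1.51 with 2 of 9 members that rose, innate-like T cell genes 1.67 with 3 of 9, and B cell genes 1.30 with 0 of 17 (camera adjusted p = 0.00311, 0.0119 and 0.00311). Double-negative thymocyte genes had a median fold of 1.54 and double-positive genes 0.805 (camera adjusted p = 0.000348 and 0.000227). Neutrophil genes had a median fold of 3.14 with 0 of 13 members that rose, and red cell genes 0.585 with 1 of 8 that fell (camera adjusted p = 0.0436 and 0.00236). Dendritic cell genes (median fold 1.41, 2 of 11 rose), thymic epithelium genes (1.38, 1 of 11), genes of the mitochondrial genome (1.20, 0 of 19) and glycolysis genes (1.14, 0 of 17) also passed (camera adjusted p = 0.00235, 0.00541, 0.00254 and 0.0436). The neutrophil score was 2.26 in labelled knockout replicate 3 and -0.99 in replicate 2, against 0.54 and -1.11 in wildtype. The single-positive, selection and adhesion lists, called over all 6 libraries, did not pass here (camera adjusted p = 0.697, 0.103 and 0.267). An estimated correlation was not run on these 4 libraries. This fit called 762 genes, and the other 2 splits of the same libraries into 2 and 2 called 0 and 0 by edgeR. They had 125 and 210 genes at an unadjusted p under 0.05 (5199 in the real split). With 3 splits no share under 0.05 can be reached. A mixed split also counts any difference between the genotypes as spread within its groups, which lowers its calls. No conclusion is drawn from this contrast.

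Genes beside those that differed were also compared, and were chosen after their values were seen. At the repeated stretch of chromosome 14, Loxl2, a matrix cross-linking enzyme, had a log2 fold of -3.31 (SE 0.524; edgeR, Benjamini-Hochberg adjusted p = 0.0564). Entpd4 had -0.84 and its copy Entpd4b -0.88 (adjusted p = 0.139 and 0.138), Slc25a37, a mitochondrial iron importer before the stretch, -0.58 (adjusted p = 0.151), and R3hcc1 and Chmp7, next along the chromosome, 0.06 and -0.13. Between Fgfbp3 and Ide on chromosome 19, Btaf1, Cpeb3 and March5 had log2 folds of 0.19, -1.39 and -0.05. None of these 9 genes passed edgeR's test over all genes with all 6 libraries. In the fit of the 4 Xist-low libraries Loxl2 and Slc25a37 passed, at log2 folds of -2.98 and -0.79 (edgeR, Benjamini-Hochberg adjusted p = 0.0368 and 0.0294).

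The 17 genes that differed between the genotypes lie at 8 places, with 10 of them on chromosome 14. The real split called 17 genes (1 of the 10 splits reached that) and the highest other 2, and 10 splits cannot give a share under 0.05. Reads shared between near-identical copies stay open for the 9 called genes that have a near-equal neighbour, since nothing in the counts tells the copies apart; the fit without such genes called 7 others. Donor sequence flanking the Il3ra allele cannot reach the 7 genes on other chromosomes. This follows from their position alone, since their places were known beforehand. It says nothing about donor sequence elsewhere in the genome, and no cause was tested for these 7 genes. Flanking donor sequence stays open for the genes on chromosome 14, the nearest 11.6 Mb away (odds ratio of 0.964 within 10 Mb, upper 95% bound 1.65). On that chromosome 7 called genes lie much farther off, between 69348897 and 69683286, with Il3ra at 14346275 to 14356011. An effect of the genotype itself was not tested.

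The cell cycle list had a median log2 fold of 0.52 in the real split (1 of the 10 splits reached that) and 0.43 in the highest other, whose camera adjusted p of 1.13e-36 was smaller than the 1.02e-32 of the real split. For the number of lists called the real split gave 17 and the others 9 to 20 (2 of the 10 splits reached 17), and 10 splits cannot give a share under 0.05. Argued against as the whole cause is a trend with GC content and transcript length (median of 0.50 after its removal, SE 0.0153). The removed trend was small, though (SD 0.04). Cycling myeloid progenitors in labelled knockout replicate 3 are also argued against as the whole cause (0.47 without it, SE 0.0222). A heat shock response in wildtype stays open. The median was 0.44 without wildtype replicate 2 (SE 0.0162), but that fit keeps replicate 3. The heat shock list scored -0.07, 0.49 and 0.23 in wildtype replicates 1 to 3. These SEs are from a bootstrap over the 37 cell cycle members, which vary together (estimated correlation 0.729), and leave out the spread between libraries. A larger share of early (double-negative) thymocytes is a candidate explanation that stays open, with a score difference of 0.31 (standard error 0.235). Labelled knockout replicate 1, though, had the lowest double-negative score (-0.28) with a cell cycle score of 0.37, and replicate 2 had scores of 0.25 and 0.02. The double-negative scores also rose over the libraries labelled knockout in the order of the macrophage and B cell scores, so they may not measure early thymocytes alone. An effect of the genotype on proliferation also stays open, as untested.

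Il3ra was not lower in the libraries labelled knockout. Splits that exchange 1 library between the genotypes called at most 2 genes, against 17 in the labelled split. This argues against such an exchange only if the genotype is what makes these genes differ, which was not tested. An allele that keeps most of the Il3ra transcript could give the fold of 1.14 (upper 95% bound 1.40), and counts summed over the gene leave it open. Wrong labels for whole groups were not tested.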
